A study of Homo sapiens with 12 samples.

How the data were processed

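Total RNA of DLD1 and HCT 116 cells, established human colorectal cancer lines, was biotin-labelled and hybridised to single-colour Affymetrix arrays, 1 per sample. The 12 samples were grouped by the line and the siRNA given in their titles and characteristics: DLD1 siControl, DLD1 siBRG1, HCT 116 siControl and HCT 116 siBRG1, 3 arrays each. The source names of 4 HCT 116 samples carry other numbers in the name of the line or of the siRNA than their titles and characteristics do; they were grouped by title, and in each the SMARCA4 level and the correlations between arrays go with the title. Nothing in the labels says whether the 3 arrays of a group came from separate cultures, so p-values measure only the spread between these samples, which may be technical. The siRNA sequences and the time after transfection are not given in the sources used here.

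The deposited values are on a log2 scale and were made by the authors with RMA in Affymetrix Power Tools, per the submitters' processing notes; versions and a genome build are not given in the sources used here. RMA subtracts background, equalises the distribution of probe intensities over arrays and summarises the probes of each feature. The table holds 21448 features, with values from 2.16 to 18.05. Between 94 and 112 values per array exceed 16, the log2 limit of a 16-bit scanner, so the scale includes a step beyond plain RMA that the labels do not name, and log2 differences are given on that scale. The sorted values of an array lay up to 0.084 (median absolute difference) from the mean distribution. The table has no detection calls, so a low value cannot be told from background here. Scan dates and slides are not in the sources used here, so batches other than the replicate number were not tested.

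Features were named through the array's annotation and current RefSeq gene symbols (matched on Entrez ID). Of them, 17709 had 1 symbol, 0 had several and 3739 had no symbol in the annotation used and were tested only as unnamed features. For the 20 genes with several features the brightest over all arrays was taken, which left 17687 genes. With no build named, no coordinates are given.

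The main analysis was limma 3.58.1 in R 4.3.3: lmFit of 4 group means over the 12 arrays and eBayes (8 residual and 6.66 prior degrees of freedom). Contrasts were siBRG1 minus siControl in each line, their average, their difference (HCT 116 change minus DLD1 change) and HCT 116 siControl minus DLD1 siControl. P-values were adjusted by Benjamini-Hochberg over all genes of a contrast, with a gene called at an adjusted p under 0.05; counts "over the list alone" repeat the adjustment within a list. SMARCA4 was also tested by an exact 2-sided permutation of array labels.

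The 28 gene lists were written from general knowledge before the data were examined: SWI/SNF subunits, intestinal cell types, signalling targets, cell cycle, stress and metabolic programmes, and markers of fibroblasts, immune and endothelial cells. They name 986 genes, of which 889 were measured and 35 stand in more than 1 list. Lists were tested with camera at a preset correlation of 0.01, adjusted over the 28 lists, and again with an estimated correlation and with fry. The genes named were fixed by rule: SMARCA4 and SMARCA2; the 10 largest rises and falls per line among called genes whose siBRG1 arrays all lay on 1 side of the siControl arrays; per list, up to 4 called members with the largest change in that line, or up to 2 members where none was called; the 5 largest rises and falls called in both lines; and the 5 largest in each direction for the difference between lines and for the control lines. Genes given in a comparison other than the 1 that selected them were chosen there after their values were seen.

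The titles number the arrays 1 to 3 in every group. In DLD1 the deviations from the group means of same-numbered siControl and siBRG1 arrays correlated across genes at 0.49, 0.46 and 0.29, all above 0.1, so the numbers were taken to pair the DLD1 arrays. That pairing comes from the data; the labels do not state it. The block was not part of the main design, and blocked values stand beside DLD1 results where they change a call or move a count by over 1.5 times.

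Alternatives were the replicate block, each line fitted alone, a further quantile normalization, centring on array medians, filters at the median and at the lower quartile of level, the mean of a gene's features, a trended and robust prior, array weights, a minimum change of 1.5-fold, an adjusted p under 0.01, the other list tests and each array left out in turn. A setting without both HCT 116 arrays numbered 1 was added after seeing the data.

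The steps were tested on simulated data with the real genes and spread. Of 50 genes changed by each amount in DLD1, the fit called 4% at a log2 change of 0.5, 60% at 1, 100% at 2 and 98% at 3, and as a difference between lines 0, 12, 82 and 92%. Of the unchanged genes among 17687, 6 were called in DLD1, 0 in HCT 116 and 7 on the difference. The simulated noise was independent between genes and between arrays, without pairing of arrays or correlation of genes. No gene was changed in HCT 116 there. These counts therefore do not give the rate of false calls in the real data. Figures were drawn with matplotlib 3.10.9.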

Results

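RNA of 2 human colorectal cancer cell lines, DLD1 and HCT 116, was measured on 12 single-colour expression arrays. Each line had been given either a control siRNA (siControl) or an siRNA against BRG1 (siBRG1), with 3 arrays for each of the 4 combinations. BRG1 is the protein product of SMARCA4, an ATPase of the SWI/SNF chromatin remodelling complexes, and the study asked what its loss does to human colorectal cancer cells. The arrays gave values for 17687 named genes. Array medians lay between 6.36 and 6.50 on the log2 scale. Across all features the correlation was 0.988 to 0.995 within a group, 0.983 to 0.994 between treatments of 1 line and 0.941 to 0.952 between lines. The number of arrays limits the precision of each value below.

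The siRNA target was low in every siBRG1 array. In DLD1, SMARCA4 (Entrez gene 6597) fell from 10.18 ± 0.20 to 6.39 ± 0.14 (log2 mean ± SD, n = 3 arrays each), a change of −3.80 (SE 0.21, limma adjusted p = 4.56e-07). In HCT 116 it fell from 9.95 ± 0.32 to 6.73 ± 0.32 (n = 3 each), a change of −3.22 (SE 0.21, limma adjusted p = 1.14e-06). The changes of the lines differed by 0.58 (SE 0.30, limma adjusted p = 0.631). A 2-sided exact permutation test gave p = 0.1 in each line, the smallest value 3 arrays against 3 can give, and p = 0.005 over both lines, again the smallest possible. SMARCA2, which encodes BRM, the alternative ATPase of the same complexes, had changes of −0.38 (SE 0.32) in DLD1 and −0.73 (SE 0.32) in HCT 116 that did not pass (limma adjusted p = 0.778 and 0.206). Its values lay between 6.69 and 7.87 in DLD1. In HCT 116 they lay between 4.14 and 5.67, below every array median, where a value cannot be told from background. The HCT 116 result therefore does not show that SMARCA2 was unchanged.

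**Figure D1:**
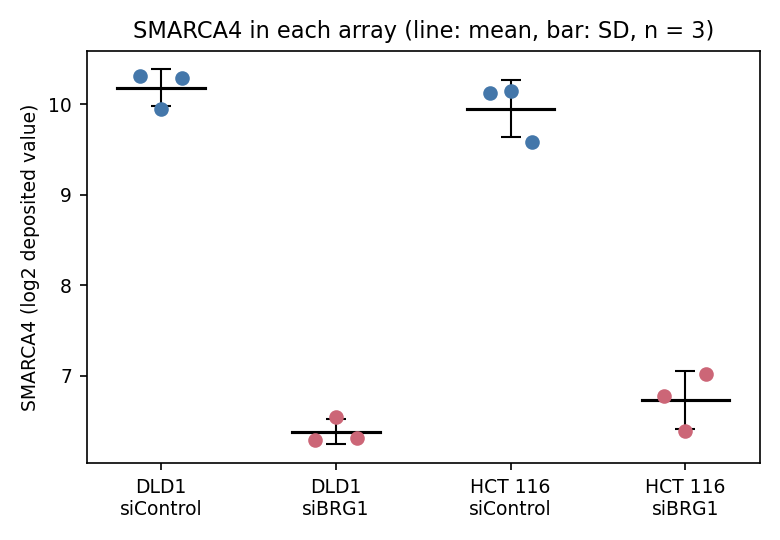
SMARCA4 in each array on the deposited log2 scale, by line and siRNA; points are arrays, lines are means and bars are SDs (n = 3). The siBRG1 arrays lie between 6.29 and 7.03 and the siControl arrays between 9.59 and 10.31.

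In DLD1, the largest rise after siBRG1 was that of CYP1A1, a cytochrome P450 induced through the aryl hydrocarbon receptor, which went from 7.24 ± 0.74 to 10.34 ± 0.94 (log2 mean ± SD, n = 3 each; change 3.09, SE 0.46, limma adjusted p = 0.01). Apart from SMARCA4, the largest fall among genes called was that of CKMT1B (−2.71, SE 0.31). CKMT1A (−2.20, SE 0.31) is a near-identical gene for mitochondrial creatine kinase, and the probes may not tell the 2 apart. LIMK1, a kinase that phosphorylates cofilin, fell by 2.33 (SE 0.27), and HSD3B1, an enzyme of steroid hormone synthesis, fell by 2.38 (SE 0.44). The rises also took in VEPH1 (1.68), the serine protease gene PRSS22 (1.53), the cofilin kinase gene TESK2 (1.43), the homeobox gene HOXB9 (1.33), SPMIP4 (1.32), CREBRF (1.30), THAP9-AS1, TRMT1L (1.14) and the aminopeptidase gene ENPEP (1.12). The falls also took in the lymphocyte receptor gene SLAMF6 (−1.88), DESI1 (−1.84), the ribosomal protein paralog RPL22L1 (−1.79), the ubiquitin ligase adaptor gene ZYG11B (−1.78) and the galactosylceramide synthesis gene UGT8 (−1.63).

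Over all 17687 genes, limma called 35 in DLD1 at an adjusted p under 0.05, 12 higher and 23 lower after siBRG1, with 1860 at an unadjusted p under 0.05. In each of the 35, all siBRG1 arrays lay on 1 side of all siControl arrays. With the replicate number as a block, 98 genes passed (41 higher and 57 lower), 32 of the 35 among them, and CREBRF did not (limma adjusted p = 0.0566). With DLD1 fitted alone 4 genes passed, all lower, and with array weights 128 did. The count was 12 without siControl replicate 1, 7 without siControl replicate 3, 8 without siBRG1 replicate 3 and 66 without siBRG1 replicate 1. It was 20, 17, 18 and 19 without HCT 116 siControl replicates 2 and 3 and siBRG1 replicates 2 and 3, which enter the shared variance. CKMT1B, KIFBP, LIMK1, SMARCA4 and ZYG11B, 5 of the 26 named genes called in DLD1, passed without any 1 of the 12 arrays.

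Of 28 gene lists fixed before the data were examined, camera with a preset correlation placed 8 lower in DLD1, and none of them held with an estimated correlation. Few of their members passed on their own. Among 58 genes of S phase (DNA replication and its licensing) none passed over all genes and 14 were lower when adjusted over the list alone. The median change was −0.31 (camera adjusted p = 1.57e-12; adjusted p = 0.396 with an estimated correlation), with CDCA7 at −1.01 and DSCC1 at −0.97. Among 33 Wnt target genes, CD44, a hyaluronan receptor, fell by 1.05 and the other 32 did not pass, 4 being lower when adjusted over the list alone (median −0.20, camera adjusted p = 3.65e-04; adjusted p = 0.193 with an estimated correlation). CD44 was also the 1 member of 29 intestinal stem cell markers that fell, with 1 higher and 4 lower adjusted over the list alone (median −0.12, camera adjusted p = 0.00977; adjusted p = 0.193 with an estimated correlation); with the replicate block, 2 of these markers were lower. Of 35 genes of the unfolded protein and amino acid response, CRELD2, a secreted protein of the endoplasmic reticulum, fell by 1.11, and 1 was higher and 2 lower adjusted over the list alone (median −0.37, camera adjusted p = 9.21e-05; adjusted p = 0.444 with an estimated correlation). With the block, 2 of that list were lower, ASNS (−1.12, blocked limma adjusted p = 0.047) being named there.

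No member passed over all genes in the other 4 lists placed lower in DLD1. The 63 genes of G2 and M phase had a median of −0.22 (camera adjusted p = 5.72e-06; adjusted p = 0.511 with an estimated correlation), with none called over the list alone, BIRC5 at −0.85 and KIF14 at −0.81. The 27 genes of cholesterol synthesis had a median of −0.46 (camera adjusted p = 9.21e-05; adjusted p = 0.555 with an estimated correlation), with none called over the list alone, the desaturase gene SCD at −1.07 and IDI1 at −0.88. The 39 MYC targets had a median of −0.10 (camera adjusted p = 0.00196; adjusted p = 0.555 with an estimated correlation), with 3 lower over the list alone, the hexokinase gene HK2 at −0.97 and PPRC1 at −0.77. The 35 genes of hypoxia and glycolysis had a median of −0.12 (camera adjusted p = 0.0236; adjusted p = 0.604 with an estimated correlation), with none called over the list alone, ADM at 0.98 and HK2 at −0.97. Leaving out siBRG1 replicate 3 lost the calls of cholesterol synthesis (median −0.03, camera adjusted p = 0.478), G2 and M phase (−0.10, 0.0889), the unfolded protein and amino acid response (−0.21, 0.0585) and hypoxia (−0.11, 0.089). Calls were also lost for the unfolded protein list without siControl replicate 2 (−0.18, camera adjusted p = 0.0586), MYC targets without siControl replicate 3 (0.207) or siBRG1 replicate 2 (−0.03, 0.112), stem cell markers without siBRG1 replicate 1 (−0.11, 0.0711). The hypoxia call was lost as well without siControl replicate 1 (0.102) or siBRG1 replicate 2 (0.0666).

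In HCT 116, the largest rise after siBRG1 was that of JUN, a subunit of the AP-1 transcription factor, which went from 6.72 ± 0.39 to 10.70 ± 0.50 (log2 mean ± SD, n = 3 each; change 3.98, SE 0.31, limma adjusted p = 5.15e-06). SNAI2, a transcriptional repressor known from epithelial-mesenchymal transition, rose by 3.56 (SE 0.34), the secretogranin gene SCG2 by 3.12 (SE 0.26) and SEMA3C, a secreted semaphorin, by 2.93 (SE 0.18). FGF19, a secreted growth factor, showed the largest fall, from 10.30 ± 0.18 to 6.05 ± 0.58 (n = 3 each; change −4.25, SE 0.28, limma adjusted p = 1.14e-06). The lower mean lies below every array median, where a value cannot be told from background, so the size of that fall is uncertain. TNS4, a focal adhesion protein, fell by 3.83 (SE 0.31) and the scavenger receptor gene SCARA3 by 3.72 (SE 0.18). Further rises were those of the nuclear receptor gene NR4A3 (2.67), the stress-induced transcription factor gene DDIT3 (2.64), AHNAK2 (2.60) and the keratin-associated genes KRTAP2-2 (3.64), KRTAP2-1 (3.50) and KRTAP2-3 (2.90), which are near-identical and may share probes. Further falls were those of the keratin gene KRT23 (−2.75), the protease gene KLK6 (−2.55), LIMK1 (−2.42), AXIN2 (−2.40), VSNL1 (−2.35) and the ion channel gene ASIC1 (−2.31).

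Limma called 1230 of the 17687 genes in HCT 116, 499 higher and 731 lower, with 3615 at an unadjusted p under 0.05. After each array was centred on its median, the split was 615 higher and 565 lower. The count was 618 without siControl replicate 2, 664 without siControl replicate 3, 675 without siBRG1 replicate 2 and 640 without siBRG1 replicate 3. HCT 116 siControl replicate 1 lay furthest from its group (root mean square deviation 0.320 log2, against 0.227 to 0.285 for the other 11 arrays). Of 95 named genes called in HCT 116, 57 passed without any 1 array.

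Target genes of p53 rose together in HCT 116. Of 35 measured, 19 rose and none fell over all genes, and 21 were higher and 2 lower when adjusted over the list alone. The cell cycle inhibitor gene CDKN1A rose by 2.59 (SE 0.43), the pro-apoptotic PMAIP1 by 2.32 (SE 0.43), ZMAT3 by 1.80 (SE 0.27) and RPS27L by 1.64 (SE 0.17). The list median was 0.66 (camera adjusted p = 4.51e-11; adjusted p = 0.00668 with an estimated correlation), the only 1 of the 6 lists called in HCT 116 that passed with an estimated correlation in the fit without a block. With the replicate block and an estimated correlation together, the p53 list did not pass (camera adjusted p = 0.256). In DLD1 no member passed, 3 were higher over the list alone, the median was −0.13, the mean 0.02 and the camera direction down (adjusted p = 0.765), with GDF15 at 1.37 and TP53INP1 at 0.91. GDF15 and TP53INP1 rose in HCT 116, by 1.57 and 1.33.

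**Figure D2:**
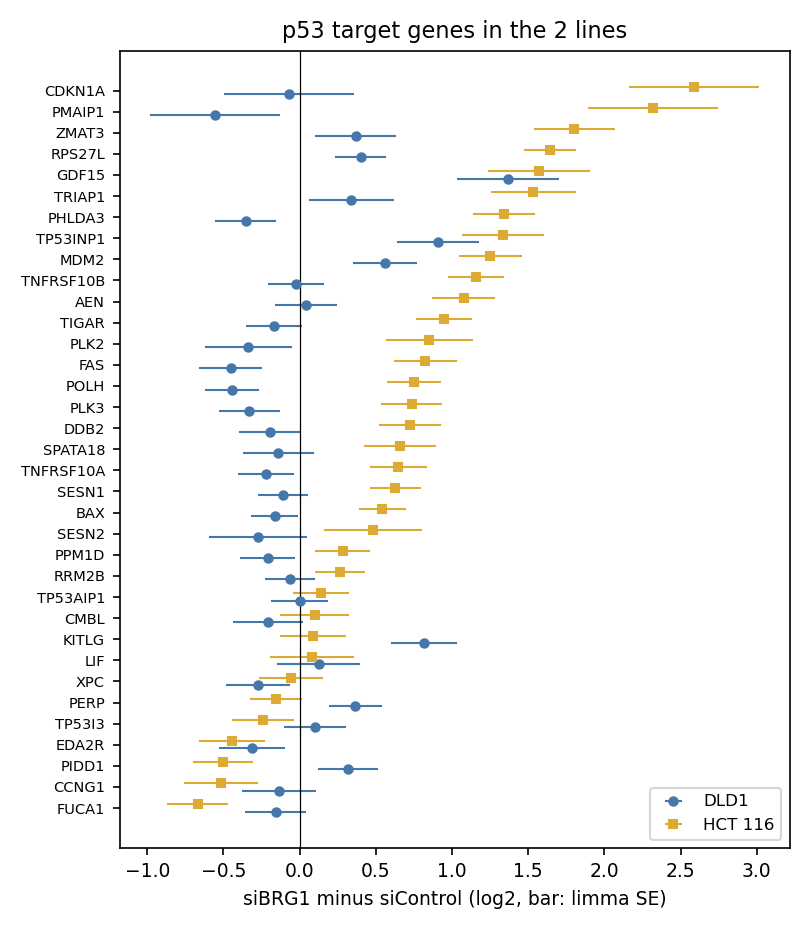
Change of each of the 35 measured p53 target genes after siBRG1 (log2, bars are limma SEs) in DLD1 (circles) and HCT 116 (squares). The list median is 0.66 in HCT 116 and −0.13 in DLD1, and CDKN1A and PMAIP1 lie furthest to the right in HCT 116.

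Response genes of MAPK and AP-1 signalling were the other list placed higher in HCT 116. Of 38 measured, 11 rose and 2 fell, against 17 higher and 3 lower adjusted over the list alone (median 0.52, camera adjusted p = 1.32e-08; adjusted p = 0.0684 with an estimated correlation). JUN led the list, EGR1 rose by 1.97 and KLF6 by 1.48, while ETV5, an ETS factor, fell by 1.46. The list was not called in DLD1 (median 0.12, camera adjusted p = 0.148), where JUN had a change of 0.98 and FOSL1 of −0.83, neither past the threshold.

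DNA replication genes were lower in HCT 116. Of 58 genes of S phase, 29 fell and none rose, and 44 were lower adjusted over the list alone (median −0.72, camera adjusted p = 1.04e-23; adjusted p = 0.102 with an estimated correlation). They took in the uracil glycosylase gene UNG (−1.74), GINS2 of the replicative helicase (−1.66), the licensing factor gene CDT1 (−1.54) and the flap endonuclease gene FEN1 (−1.48). Of 63 genes of G2 and M phase, 6 fell, among them BIRC5 (−1.72), TACC3 (−1.21), CDCA5 (−0.89) and the spindle checkpoint kinase gene TTK (−0.80), and 10 were lower over the list alone (median −0.33, camera adjusted p = 4.94e-07; adjusted p = 0.503 with an estimated correlation).

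Of 35 genes of the unfolded protein and amino acid response, 9 fell and 3 rose, against 14 and 3 over the list alone (median −0.42, camera adjusted p = 4.47e-04; adjusted p = 0.503 with an estimated correlation). The serine synthesis genes PHGDH (−2.23) and PSAT1 (−1.85) and the asparagine synthetase gene ASNS (−2.04) fell, whereas DDIT3 of the same list rose. Of 27 genes of cholesterol synthesis, the regulator gene SREBF2 (−1.29), FDPS (−1.13) and the elongase gene ELOVL6 (−0.77) fell, and 9 were lower over the list alone (median −0.79, camera adjusted p = 1.01e-05; adjusted p = 0.507 with an estimated correlation).

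Intestinal stem cell markers and Wnt targets, which bear on the study's subject of tumour stem cells, were not called as lists in HCT 116 by camera with the preset correlation. Of 29 stem cell markers, 4 fell and none rose, over all genes and over the list alone: CD24 (−1.60), the RNA-binding MSI1 (−1.29), the Wnt receptor ligase gene RNF43 (−1.14) and the crypt transcription factor gene SOX9 (−0.95). The list median was −0.18 (camera adjusted p = 0.0561). The list was placed lower under 8 alternatives, among them HCT 116 fitted alone (adjusted p = 0.0462), centring (0.0492), genes above the median level (0.0438) and fry (0.003), but not with an estimated correlation (adjusted p = 0.168). Of 33 Wnt targets, 5 fell and 1 rose, against 9 and 3 over the list alone (median −0.12, camera adjusted p = 0.156; fry adjusted p = 0.0387). AXIN2, a negative feedback gene of the Wnt pathway, fell from 10.24 ± 0.08 to 7.83 ± 0.18 (log2 mean ± SD, n = 3 each), CEMIP fell too, and DKK1, a secreted Wnt antagonist, rose by 2.51 (SE 0.33).

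**Figure D3:**
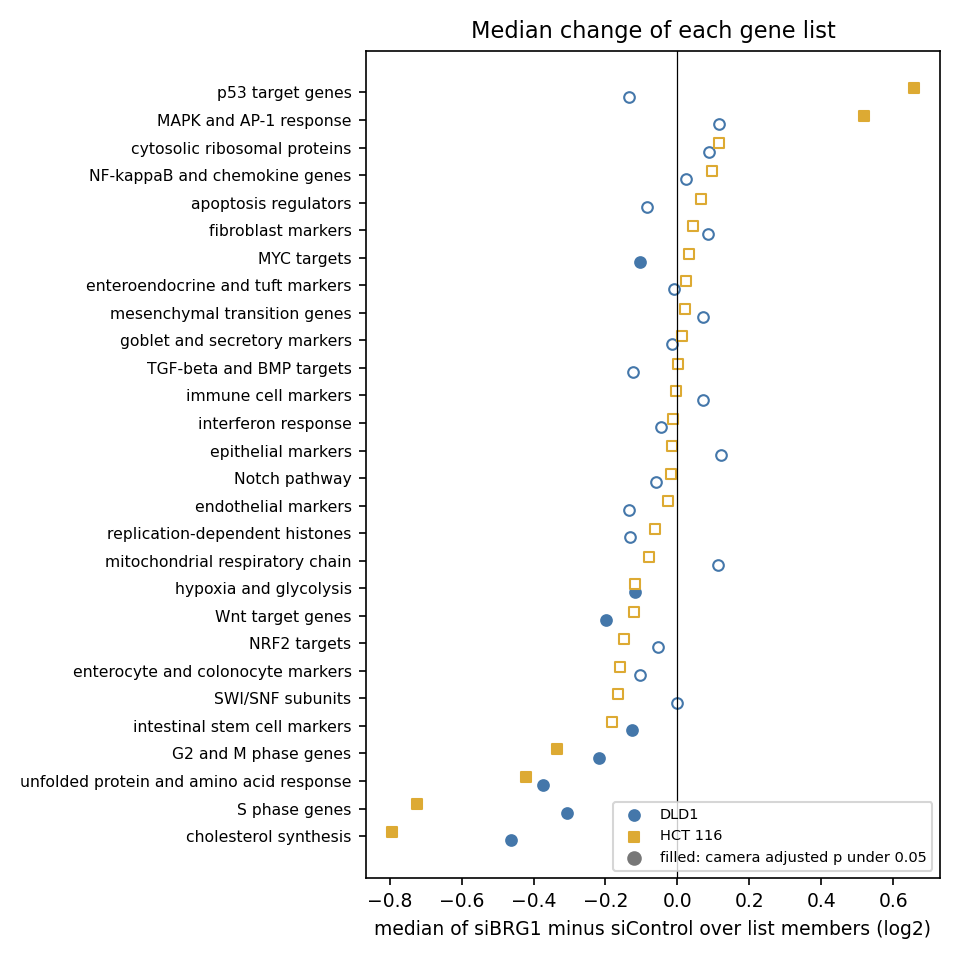
Median change of the members of each of the 28 gene lists after siBRG1 (log2) in DLD1 (circles) and HCT 116 (squares); filled symbols mark a camera adjusted p under 0.05 with the preset correlation. Medians run from −0.79 for cholesterol synthesis to 0.66 for p53 target genes, both in HCT 116.

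SMARCA4, LIMK1 and ZYG11B fell in both lines. LIMK1 changed by −2.33 in DLD1 and −2.42 in HCT 116, ZYG11B by −1.78 and −1.66, the kinesin-binding KIFBP by −1.39 and −1.81, and the desumoylating peptidase gene DESI1 by −1.84 and −1.23. The rises called in both lines were those of AHNAK2 (1.08 in DLD1 and 2.60 in HCT 116), SPMIP4 (1.32 and 0.80), TRMT1L (1.14 and 0.92), THAP9-AS1 (1.25 in HCT 116) and CREBRF (1.30 in DLD1). Without 1 array, the DLD1 calls of AHNAK2, THAP9-AS1 and CREBRF stood in 3 of 12 fits. That of TRMT1L stood in 4 and that of SPMIP4 in 10. With the replicate block CREBRF did not pass in DLD1 (limma adjusted p = 0.0566). In all, 17 genes were called with the same direction in both lines, 5 higher and 12 lower, the siRNA target SMARCA4 among the latter. Independent lists would share 0.339 and 0.951. The lines have separate controls, but their fit shares an estimate of the spread of each gene, so the calls are not independent. With each line fitted alone 3 genes were shared, all lower. TESK2 was called in opposite directions, 1.43 in DLD1 and −0.85 in HCT 116. Of the 1230 genes called in HCT 116, 1020 (82.9%) had the same sign in DLD1. Across all genes, which are not independent replicates, the changes of the lines correlated with Pearson's r of 0.402 and Spearman's rho of 0.353.

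On average over both lines limma called 1536 genes, 709 higher and 827 lower. With the replicate block it called 2476, and the genes shared in direction numbered 49. The shared count of 17 became 7 without DLD1 siControl replicate 1, 4 without DLD1 siControl replicate 3, 31 without DLD1 siBRG1 replicate 1, 4 without DLD1 siBRG1 replicate 3, and 6, 7, 7 and 6 without HCT 116 siControl replicates 2 and 3 and siBRG1 replicates 2 and 3. The average count became 1013 without DLD1 siControl replicate 3, 797 without DLD1 siBRG1 replicate 3, and 935, 982 and 1000 without HCT 116 siControl replicate 2 and siBRG1 replicates 2 and 3.

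**Figure D4:**
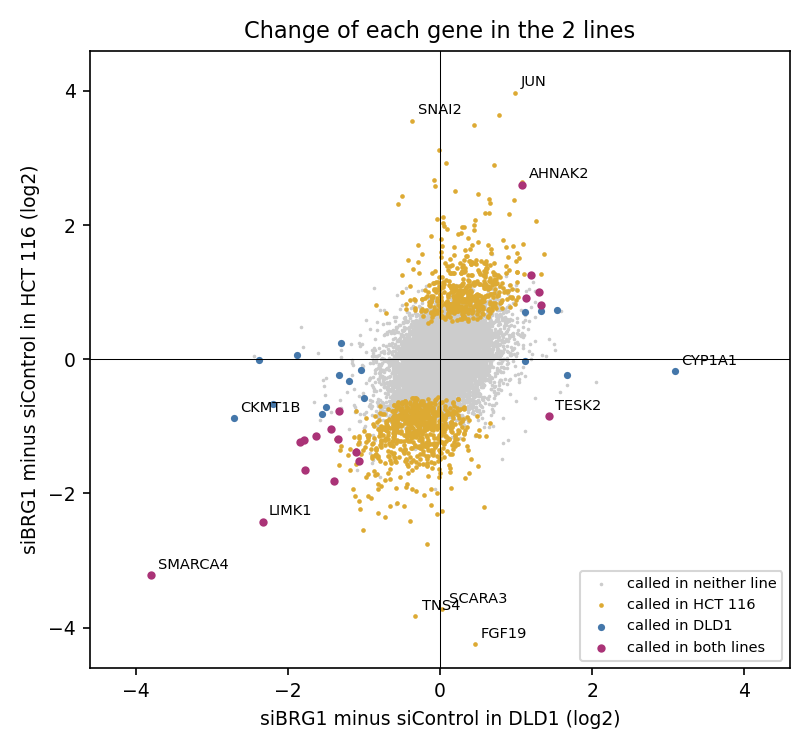
Change of each gene after siBRG1 in DLD1 (x axis) and HCT 116 (y axis), log2, coloured by the line in which limma called it at an adjusted p under 0.05. SMARCA4 and LIMK1 lie low on both axes, JUN and SNAI2 are high in HCT 116, and CYP1A1 is high in DLD1.

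The test of the difference between the lines was passed by genes that changed in HCT 116, such as FGF19, and by genes that changed in DLD1, such as CYP1A1. FGF19 changed by −4.25 in HCT 116 and 0.45 in DLD1 (difference −4.70, SE 0.39, limma adjusted p = 5.24e-05), SCARA3 by −3.72 and 0.03 (difference −3.75, SE 0.26) and TNS4 by −3.83 and −0.33 (difference −3.50, SE 0.43). SNAI2 changed by 3.56 in HCT 116 and −0.38 in DLD1 (difference 3.94, SE 0.48, limma adjusted p = 0.00195), and SCG2, JUN, KRTAP2-1 and the nuclear receptor gene NR4A2 had differences of 3.13, 2.99, 3.05 and 2.93. CYP1A1, which rose in DLD1, had a change of −0.18 in HCT 116 (difference −3.27, SE 0.64, limma adjusted p = 0.0464), and ANTXR1, an anthrax toxin receptor, changed by −2.20 and 0.58 (difference −2.78). Among stem cell and Wnt genes, the difference was −2.01 for AXIN2, −1.61 for SOX9, −1.64 for MSI1 and 2.31 for DKK1. The level of each gene in the line where it changed little was not weighed here. A change near 0 can also come from a gene that cannot be told from background in that line.

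The difference was called for 59 genes, 28 with a higher and 31 with a lower change in HCT 116, and for 1590 at an unadjusted p under 0.05. The split was 40 and 19 after centring each array on its median, and 102 genes passed with the replicate block, where MSI1 (limma adjusted p = 0.0524) and RPS27L (0.0519) did not. The block instead gained CDKN1A (limma adjusted p = 0.0251), PMAIP1 (0.00489), UNG (0.0411), SKIL (0.0205), CD24 (0.047), RNF43 (0.0431), GALNT12 (0.0149), HES1 (0.00397), OLR1 (0.0205), VSNL1 (0.0318), HSD3B1 (0.0366) and ABCC3 (0.0411). With it, 5 p53 targets, 2 apoptosis regulators and 1 S phase gene were called on the difference. Of 24 named genes called on the difference, 14 passed without any 1 of the 12 arrays. RPS27L passed in 0 of the 12 fits, ANTXR1 in 1, MSI1 and DKK1 in 2, CYP1A1 and AHNAK2 in 3, SOX9 and VEPH1 in 9, and EGR1 and NR4A2 in 11. The count was 38 without DLD1 siControl replicate 1, 26 without DLD1 siControl replicate 3, 37 without DLD1 siBRG1 replicate 3, and 29, 30 and 26 without HCT 116 siControl replicates 2 and 3 and siBRG1 replicate 3. Of 5 lists called on the difference, the p53 targets also passed with an estimated correlation, though not with the block as well (adjusted p = 0.183; median difference 0.74, 2 members called higher over all genes, 17 higher and 1 lower over the list alone, camera adjusted p = 7.92e-13; adjusted p = 0.00366 with an estimated correlation). The MAPK and AP-1 genes (median 0.41, camera adjusted p = 1.96e-07; adjusted p = 0.103 with an estimated correlation) had 2 members called higher over all genes, and 12 higher and 2 lower over the list alone. S phase genes (median −0.39, camera adjusted p = 4.49e-08; adjusted p = 0.452 with an estimated correlation) and MYC targets (0.22, camera adjusted p = 0.0031; adjusted p = 0.673 with an estimated correlation) had no member called either way without the block. Apoptosis regulators (0.08, camera adjusted p = 0.00645; adjusted p = 0.224 with an estimated correlation) had none over all genes without the block, and 7 higher and 1 lower over the list alone. The apoptosis list shares members with the p53 list, PMAIP1 and TNFRSF10B among them. Without 1 array the call of the apoptosis list was lost (HCT 116 siBRG1 replicate 2, camera adjusted p = 0.0714), as was that of the MYC targets (DLD1 siControl replicate 3, 0.14; DLD1 siBRG1 replicate 2, 0.065). The respiratory chain list was not called (0.0586), but was called lower with the block (0.0335; adjusted p = 0.711 with an estimated correlation and the block), with a trended, robust prior (0.0198) and without each of 6 single arrays, with the lowest value without DLD1 siBRG1 replicate 2 (0.0014).

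The control arrays show how the lines differ without knockdown. GTSF1, a piRNA pathway factor, was at 14.88 ± 0.21 in HCT 116 and 3.46 ± 0.44 in DLD1 (log2 mean ± SD, n = 3 each; limma adjusted p = 2.96e-13). DMKN, the drug transporter gene ABCC2, the scramblase gene ANO6 and SLC38A5 were also higher in HCT 116. The chemokine gene CXCL5 was at 4.48 ± 0.18 in HCT 116 and 15.59 ± 0.20 in DLD1 (n = 3 each). The membrane protein gene TM4SF1, the lipoprotein receptor gene OLR1, QPCT and the nuclear receptor gene RORA were lower in HCT 116 too. In each of these the lower line lies where a value cannot be told from background, so no size of difference or ranking is given. In all, 4884 genes differed, 2402 higher and 2482 lower in HCT 116. Of 32 epithelial markers, 21 were lower and 2 higher in HCT 116, 22 and 2 over the list alone (median −0.87, camera adjusted p = 4.07e-08; adjusted p = 0.029 with an estimated correlation), the claudin gene CLDN2 being at 5.38 in HCT 116 and 11.45 in DLD1 and the splicing factor gene ESRP1 going the other way, at 14.49 and 10.10. Of 52 interferon response genes, 22 were lower and 6 higher, 26 and 7 over the list alone (median −0.56, camera adjusted p = 1.21e-04; adjusted p = 0.029 with an estimated correlation), with OAS1 at 3.99 in HCT 116 and 10.04 in DLD1.

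Camera called 7 more lists between the control lines that were lost with an estimated correlation. Replication-dependent histones (10 lower and 1 higher of 28 over all genes, 12 and 1 over the list alone, camera adjusted p = 1.85e-05; adjusted p = 0.26 with an estimated correlation), cholesterol synthesis (15 and 1 of 27, 17 and 1 over the list alone, 4.08e-04; 0.679 with an estimated correlation), Wnt targets (15 and 9 of 33 either way, 0.0408; 0.289 with an estimated correlation) and goblet and secretory markers (9 and 0 of 29 either way, 0.0391; 0.138 with an estimated correlation) were lower in HCT 116. So were NF-kappaB and chemokine genes (10 and 1 of 36, 11 and 1 over the list alone, 0.022; 0.104 with an estimated correlation) and the unfolded protein and amino acid response (8 and 0 of 35 either way, 0.0216; 0.679 with an estimated correlation). Mesenchymal transition genes were higher (14 higher and 7 lower of 38, 15 and 8 over the list alone, camera adjusted p = 0.0473, and adjusted p = 0.195 with an estimated correlation).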

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

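The tests of spread, knockdown strength, replicate number, single arrays, scaling, stress and shared falls were chosen after the results they bear on had been seen; the regroupings of gene and list counts and the first comparison of the size of changes were fixed before their outcome was known. The regroupings of single lists were added later, for the 5 lists called on the real labels and after the regrouping of the list count had been seen. The regroupings that respect the DLD1 number pairs were added after those that do not had been seen, and the size comparison with DLD1 arrays paired was added after the first 1 had been seen.

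The response to siBRG1 differed between the lines for 59 genes by the test of the difference itself. When the line labels were permuted within each treatment, after removal of each line's mean, 1 of 100 regroupings (the real one) gave as many, the highest other giving 2. These did not keep the DLD1 number pairs. Of the 28 regroupings that move same-numbered DLD1 arrays together, 1 (the real one) gave as many, the highest other giving 0. That is the smallest share these regroupings can give, so other groupings of these arrays seldom gave as many calls. They cannot exclude chance between cultures, since the arrays of a group may be technical repeats.
Among the genes named, the HCT 116 change exceeded that of DLD1 for SNAI2 (3.94), SCG2 (3.13), KRTAP2-1 (3.05), JUN (2.99), NR4A2 (2.93), KRTAP2-2 (2.87), SEMA3C (2.86), NR4A3 (2.75), DKK1 (2.31), EGR1 (1.68), AHNAK2 (1.52) and RPS27L (1.24), all on the log2 scale. It lay below that of DLD1 for FGF19 (−4.70), SCARA3 (−3.75), TNS4 (−3.50), CYP1A1 (−3.27), ANTXR1 (−2.78), KRT23 (−2.57), TESK2 (−2.28), ASIC1 (−2.27), AXIN2 (−2.01), VEPH1 (−1.91), MSI1 (−1.64) and SOX9 (−1.61). Of these 24 calls, 14 stood without any 1 array, and those of RPS27L, ANTXR1, MSI1, DKK1, CYP1A1 and AHNAK2 stood in 3 of 12 fits or fewer.

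Of the gene lists, 5 were called on the difference, with median differences of 0.74 for p53 targets, 0.41 for MAPK and AP-1 genes, 0.22 for MYC targets, 0.08 for apoptosis regulators and −0.39 for S phase genes. With an estimated correlation only the p53 list passed (adjusted p = 0.00366, and 0.183 with the block as well), the others having adjusted p = 0.103, 0.673, 0.224 and 0.452 in that order. The number of lists is no evidence by itself, since 62 of the 100 regroupings called as many and the highest other called 11, so chance is not excluded for it. List by list, the camera p was as small in 1 of 100 regroupings for p53 targets (2.83e-14, lowest other 1.17e-09), 2 for MAPK and AP-1 genes (2.11e-08, lowest other 2.96e-09) and 1 for apoptosis regulators (0.00115, lowest other 0.00139). It was as small in 12 for S phase genes (3.21e-09, lowest other 3.55e-17) and 21 for MYC targets (4.42e-04, lowest other 2.89e-08). These shares are not corrected for the choice among 28 lists, and the regroupings do not keep same-numbered DLD1 arrays together, so chance is left open for every list. The apoptosis and p53 lists share members, such as PMAIP1 and TNFRSF10B, so their results are not separate.

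Within a line, 3 arrays against 3 make 10 splits, too few for a share under 0.05. As large a result came in 1 split for DLD1 genes (35, highest other 15), 1 for HCT 116 genes (1230, highest other 0), 1 for control-line genes (4884, highest other 0), 2 for DLD1 lists (8, highest other 8) and 2 for HCT 116 lists (6, highest other 6). Every other split called lists, at least 4 in DLD1 and at least 2 in HCT 116. Camera with the preset correlation thus called lists on arbitrary labels too. Among the 4 splits of DLD1 that part all number pairs, the highest other count was 0 genes and 6 lists; the split with 15 genes keeps 2 number pairs together. Over both lines, relabelling treatment within each line gave as many average calls in 1 of 100 regroupings (1536, highest other 140) and as many shared calls in 1 of 100 (17, highest other 1), with DLD1 number pairs disregarded. Among the 80 regroupings that part all 3 DLD1 number pairs, as many came in 1 for each (highest other 276 and 1). Arbitrary treatment labels thus seldom gave either count, which speaks only against no response to treatment at all. Relabelled fits called few or no genes within a line. They could therefore not show whether the lines share more genes than 2 separate responses would.

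Far fewer genes were called in DLD1 than in HCT 116. The tables argue against a larger spread between DLD1 arrays (root mean variance 0.981 times that of HCT 116). They also argue against a shift shared by same-numbered arrays as the whole cause. With the block DLD1 still had 4.62% of the HCT 116 count (98 against 2123, and 35 against 1230 without it). A part played by such a shift stays open. The SMARCA4 change in HCT 116 minus that in DLD1 was 0.58, so on the deposited scale the fall was no smaller in DLD1. Knockdown strength cannot be ranked from this, since SMARCA4 after siBRG1 in DLD1 (6.29 to 6.55) lay near the array medians and may be background. The changes themselves were smaller: with the noise variance taken out, their SD over genes in DLD1 was 0.522 times that in HCT 116, and 0.0619 to 0.734 times without any 1 array; with the DLD1 noise taken from same-numbered arrays it was 0.692 times, and 0.526 to 0.775 without any 1 DLD1 pair or HCT 116 array. A biological difference between the lines may lie behind this and was not tested, and the time after transfection and the protein level stay open.

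Target genes of p53 were higher after siBRG1 in HCT 116. The tables argue against a single array (lowest list median 0.62 without any 1 array) and against unfolded protein or amino acid stress as a whole. The list of that stress had a median of −0.42 with more members lower than higher, although DDIT3 rose. After centring each array the p53 list median was 0.72. Array medians lay between 6.36 and 6.50, so centring could move the list only slightly, and it cannot decide on other effects of scaling. A candidate explanation is the known difference in p53 function between these lines, a hypothesis that the design, with 1 line of each kind, cannot test.

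Several genes fell by similar amounts in both lines, LIMK1 and ZYG11B among them. A direct effect of the siRNA on other transcripts could lower the same genes in both lines. Without SMARCA4, 11 of 22 genes lower in DLD1 were also lower in HCT 116, against 5 of 12 higher in both (2-sided Fisher's exact test p = 0.729, odds ratio 1.39, 95% interval 0.275 to 7.45). With so few genes and no siRNA sequence, an off-target effect and a response to BRG1 loss cannot be told apart.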

How the results depend on the processing

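The SMARCA4 change stayed between −3.92 and −3.74 in DLD1 and between −3.40 and −3.05 in HCT 116 without any 1 array. The count between the control lines moved by less than 1.5 times under each alternative run for it, which leaves out the block and the lines fitted alone. The cause of the shifts below was not tested.

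With the replicate block the counts were 98 in DLD1, 2123 in HCT 116, 2476 on average, 102 for the difference and 49 shared. In HCT 116 same-numbered arrays correlated at 0.30, 0.15 and 0.03, and replicate 3 correlated better with another number (0.23); 1222 of the 1230 genes were among the 2123. Of 143 named-gene calls in the blocked contrasts, 140 remained. Within the lines 18 calls were gained, a count that leaves out the gains on the difference given above. With the block and an estimated correlation together, the p53 list passed neither in HCT 116 (adjusted p = 0.256) nor on the difference (0.183); the stem cell markers passed in HCT 116 with the block (0.0339; adjusted p = 0.381 with an estimated correlation). Each line fitted alone called 4 genes in DLD1 and 3 shared. Genes above the median level gave 29 shared and 5 DLD1 lists. A trended, robust prior gave 63 in DLD1 and 33 shared. Array weights, lowest for HCT 116 siControl replicate 1 (0.436), gave 128 in DLD1, 2035 in HCT 116, 2306 on average, 162 for the difference and 61 shared. An adjusted p under 0.01 left 11, 418, 494, 16 and 5. Camera with an estimated correlation called 0 lists in DLD1, 1 in HCT 116 and 1 on the difference, and fry 1, 7 and 2. Of the lists camera called in HCT 116, fry kept p53 targets (fry adjusted p = 2.1e-05), MAPK and AP-1 genes (9.27e-04) and S phase genes (9.27e-04). It lost G2 and M phase (0.059), cholesterol synthesis (0.184) and the unfolded protein and amino acid response (0.0867). In DLD1 fry called only the stem cell markers (0.0457). Without both HCT 116 arrays numbered 1, a setting chosen after seeing the data, 11 genes were shared.

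Without each array in turn, counts ran from 7 to 66 in DLD1, 618 to 1271 in HCT 116, 797 to 1593 on average, 26 to 71 for the difference, 4 to 31 shared, 5 to 8 DLD1 lists and 4 to 9 lists on the difference; 5 and 9 came without DLD1 siBRG1 replicate 3. The median of the NRF2 targets in DLD1 (−0.05) ran from −0.21 without siControl replicate 3 to 0.35 without siControl replicate 2 (camera adjusted p = 0.019 and 8.54e-04). Of 350 values for named genes, 153 passed. Of these, 146 still did after quantile normalization, 144 after centring and 104 to 142 without 1 array, and none reversed. With each line fitted alone, 87 of the 119 calls covered there remained, 32 were lost and 6 were gained.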

Other observations

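The test of scaled-down changes was fixed before its outcome was known; its form with DLD1 arrays paired was chosen only after that result had been seen.

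In HCT 116, other members of the fixed lists changed without a call for the list. Of 28 SWI/SNF subunits, BCL7B (−1.30), SMARCD3 (−1.10) and BRD7 (−0.69) fell, 1 higher and 4 lower over the list alone (median −0.16, camera adjusted p = 0.0801, but 0.0462 with HCT 116 fitted alone, 0.0353 with fry, and 0.0455 and 0.0329 without siControl replicate 3 and siBRG1 replicate 1; adjusted p = 0.409 with an estimated correlation); BCL7B also stood at −1.30 in DLD1, where it passed with the replicate block (limma adjusted p = 0.0329). Of 27 NRF2 targets, the heme oxygenase gene HMOX1 (2.38) and GCLC, a glutathione synthesis gene, rose, while the transporter genes ABCC3 (−1.77) and ABCC2 (−1.46) fell (3 lower and 2 higher in all, 4 and 2 over the list alone, camera adjusted p = 0.527). Of 36 apoptosis regulators, 7 rose, with BIRC2 (1.46) and the death receptor gene TNFRSF10B (1.16) among them, and 3 fell, with BIRC5 (−1.72) among them, 9 and 4 over the list alone (camera adjusted p = 0.154). Of 38 mesenchymal transition genes, SNAI2, ZEB1 (1.43) and ACTA2 (0.89) rose and ITGA5 (−0.87) fell, 5 and 4 over the list alone (camera adjusted p = 0.376), and of 32 epithelial markers ESRP1 (−1.17) and GRHL2 (−0.91) fell and OCLN (0.60) rose, 3 and 1 over the list alone (0.628). Of 26 TGF-beta and BMP targets, SKIL (1.84) and JUNB (0.87) rose and SMAD6 (−1.26) and SMAD7 (−1.07) fell, 2 and 3 over the list alone (0.628).

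Fewer members moved in the remaining HCT 116 lists. The Notch genes DTX4 (−1.01) and JAG1 fell (camera adjusted p = 0.733), as did the enterocyte peptidase gene DPP4 (−1.46; 0.277), the mucin glycosylation gene GALNT12 of the goblet list (−2.19; 0.960), the interferon genes OAS3 (−1.06) and UBE2L6 (−0.81; 0.910), the glycolytic PFKL (−1.53) and CA12 (−0.88; 0.171) and the respiratory SDHA (−0.68; 0.511), which did not pass over its list alone. The hypoxia and glycolysis list (3 lower over the list alone; adjusted p = 0.828 with an estimated correlation) had a median of −0.12 that depended on single arrays: −0.30 without siControl replicate 1 (camera adjusted p = 0.00253), −0.20 without siBRG1 replicate 2 (0.0456) and near 0 without siControl replicate 3 (0.886). SCG2 rose and IL17RB (−1.39) fell among enteroendocrine and tuft markers (0.376), and IL18 (0.91) rose and TNFAIP2 (−1.18) fell among NF-kappaB and chemokine genes (0.277), where none passed over the list alone. Limma called no MYC target (camera adjusted p = 0.603), ribosomal protein (0.154) or replication-dependent histone (0.277) gene in HCT 116, with HK2 at −0.78, RPL10A at −0.37 and H2BC14 at −1.65. Of the markers of other cell types, CD68 (1.29) rose among immune markers (0.376), and no fibroblast (0.860) or endothelial (0.733) marker passed.

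In DLD1, KLK1 of the goblet list fell (camera adjusted p = 0.123), as did OAS1 of the interferon list (−1.31; 0.370). With the replicate block, 2 goblet markers passed, and CLDN2 (−1.51, limma adjusted p = 0.0409) of the epithelial list and ID3 (−1.15, 0.0409) of the TGF-beta list fell. Without the block no member passed in the lists of SWI/SNF subunits (0.888), Notch (0.166), enterocyte (0.104), enteroendocrine (0.888), apoptosis (0.123), epithelial (0.370), TGF-beta (0.125), NF-kappaB (0.502), NRF2 (0.892), ribosomal (0.232), respiratory (0.104) and histone (0.104) genes, nor among fibroblast (0.688), immune (0.888) or endothelial (0.232) markers, and CD44 was the 1 mesenchymal gene that fell (0.604). Median and mean differed in sign, without a call, for the goblet list in HCT 116 (0.01 and −0.06), where the test pointed down, and for the immune markers in DLD1 (0.07 and −0.01), also down. The same held for the immune (median near 0, mean 0.11) and fibroblast (0.04 and −0.01) markers in HCT 116, both with the test up, and for the enteroendocrine markers in DLD1 (−0.01 and 0.01), with the test down. Of the 3739 unnamed features, limma called 4 in DLD1, 61 in HCT 116 and 2 on the difference.

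A hypothesis was that the DLD1 response is the HCT 116 response scaled down, so that the changes would correlate above 0.9 once noise is taken out of both variances. With the noise estimated within groups the correlation was 0.822, against 0.399 without that correction (SMARCA4 left out of both), and the slope of DLD1 on HCT 116 was 0.429. Without any 1 array the corrected correlation ran from 0.691 to 5.21, the highest without DLD1 siBRG1 replicate 3, where little variance is left in DLD1 after the correction. That estimate ignores the pairing of the DLD1 arrays, which inflates the DLD1 noise. With the DLD1 noise taken from same-numbered arrays, the correlation was 0.62, and 0.568 to 0.668 without any 1 DLD1 pair or HCT 116 array, below the 0.8 set as the bound, so if the numbers pair in DLD1 the values argue against a purely scaled response. Genes called higher in HCT 116 had a median change of 0.33 in DLD1 and those called lower −0.31.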
